A study of Homo sapiens and Mus musculus with 28 samples.

How the data were processed

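RNA from 4 mouse HNSCC tumors and 24 SCC1 cultures was sequenced. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I, enriched with oligo(dT) beads, fragmented and primed with random hexamers, and sequenced on an Illumina HiSeq instrument at BGI. The labels name the molecule as genomic DNA, which does not go with that protocol, and the values were read as RNA. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.4, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.42.0, with builds mm10 and hg38. The annotation and the strand setting are not given in the sources used here.

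The deposited files hold raw counts per Ensembl gene ID, 1 library per file, checked to be whole numbers. An ID with several symbols repeats its count on several lines, and each ID was used once, which left 32138 mouse and 35135 human IDs. All 35135 human IDs were found in the gene name table, and mouse symbols were taken from the files. Depth per library ran from 16.73 to 18.19 M counts in mouse and from 16.04 to 27.94 M in SCC1. All 13 mitochondrially encoded mRNAs are listed at 0 in SCC1. Intervals and floors cover counting error only, with a confidence level of 0.95 and a floor of 3 counts over a group.

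Groups were taken from the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10, quasi-likelihood F tests, Benjamini-Hochberg adjustment, threshold 0.05). The mouse libraries, the 15 libraries of the knockout experiment and the 9 of the iR4 experiment were fitted apart, and all 24 SCC1 libraries together for the differences between experiments. There were 7 main comparisons and 7 secondary ones. The labels do not say what a replicate is, so p-values in SCC1 may measure only technical spread between libraries.

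Gene lists, 29 human and 43 mouse, were written from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. They cover interferon and nucleic acid sensing, antigen presentation, cytokines, stress, metabolism, cell cycle, DNA repair, R-loops, m6A, ribosomes and, in mouse, cell types. Lists with at least 3 tested members were tested on limma 3.58.1 voom values with camera (preset correlation 0.01, adjusted over the lists of a comparison), with an estimated correlation and with fry as alternatives. Named genes are the targeted gene, the 6 largest rises and 6 largest falls among genes past the threshold with an average log2 CPM of at least 2 and no overlap between groups, up to 2 members for each of the 5 strongest lists, the 2 lowest-p members of 4 immune lists, and in mouse the lowest-p member of each cell type list. ESM1, PXDN, SLC12A3 and others shown again in a comparison that did not select them were named there after their values were seen.

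Shared controls were handled by simulating unchanged groups around the control mean, 20 times. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter, a stricter filter of 1 CPM, robust dispersion, a fold minimum, the replicate number as a block, other sets of libraries in the fit, and leaving out each replicate. The tests were also run on simulated data. For R4KO_1 against Ctrl, edgeR recovered 80.6% of genes changed 1.5-fold and 89.6% of genes changed 2-fold among 14151 tested, with 15 false calls. At 2-fold it recovered 88.1% for R4KO_2 (10 false calls), 85.1% for H-151 in KO_2 cells (11), 83.6% for BX-795 (11), 88.1% for iR4 (21) and 94.0% for H151_iR4 (14). For the mouse comparison it recovered 0 of 67 genes changed 2-fold and 1 of 66 changed 4-fold among 14141 tested, where DESeq2 recovered 33.3% of the latter with 44 false calls.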

Results

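Polyadenylated RNA was sequenced from 28 libraries in 10 groups to ask what loss of the RNA exonuclease REXO4 does to gene expression in head and neck squamous cell carcinoma (HNSCC). The 4 mouse libraries came from autochthonous HNSCC tumors, 2 from Rexo4-knockout (R4KO) and 2 from wild-type (Wt) tumors. The other 24 libraries came from SCC1, an established human HNSCC cell line, with 3 libraries in each of 8 groups. A first SCC1 experiment of 15 libraries held control cells with vehicle (Ctrl Vehicle), the knockouts R4KO_1 and R4KO_2 with vehicle, and KO_2 cells with H-151 or BX-795. H-151 is a covalent inhibitor of the innate immune adaptor STING, and BX-795 inhibits the kinase TBK1, which acts downstream of STING, along with other kinases. A second SCC1 experiment of 9 libraries held Vehicle, iR4 and H151_iR4 cells; iR4 is written here as the labels give it. Total counts ran from 16.73 to 18.19 M per mouse library and from 16.04 to 27.94 M per SCC1 library.

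The targeted gene was looked at in every library first. In SCC1, REXO4 (ENSG00000148300) stood at 74.99 ± 3.01 CPM (TMM-scaled; mean ± SD, n = 3) in Ctrl Vehicle, 9.58 ± 0.354 in R4KO_1 and 6.40 ± 1.18 in R4KO_2, so that some transcript remained in both knockouts. KO_2 cells given H-151 or BX-795 held more of it, 18.1 ± 1.49 and 19.1 ± 0.449 CPM. In the iR4 experiment REXO4 was at 94.0 ± 3.43 CPM in Vehicle, 60.2 ± 2.84 in iR4 and 89.5 ± 2.21 in H151_iR4. In the tumors, Rexo4 (ENSMUSG00000052406) was at 17.4 and 14.9 CPM in the R4KO libraries and at 31.1 and 30.3 CPM in the Wt libraries. REXO4 lies on the minus strand of chromosome 9 from 133406059 to 133418096 in GRCh38 (GENCODE v29), where STKLD1 and ADAMTS13 overlap its ends on the other strand.

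**Figure D1:**
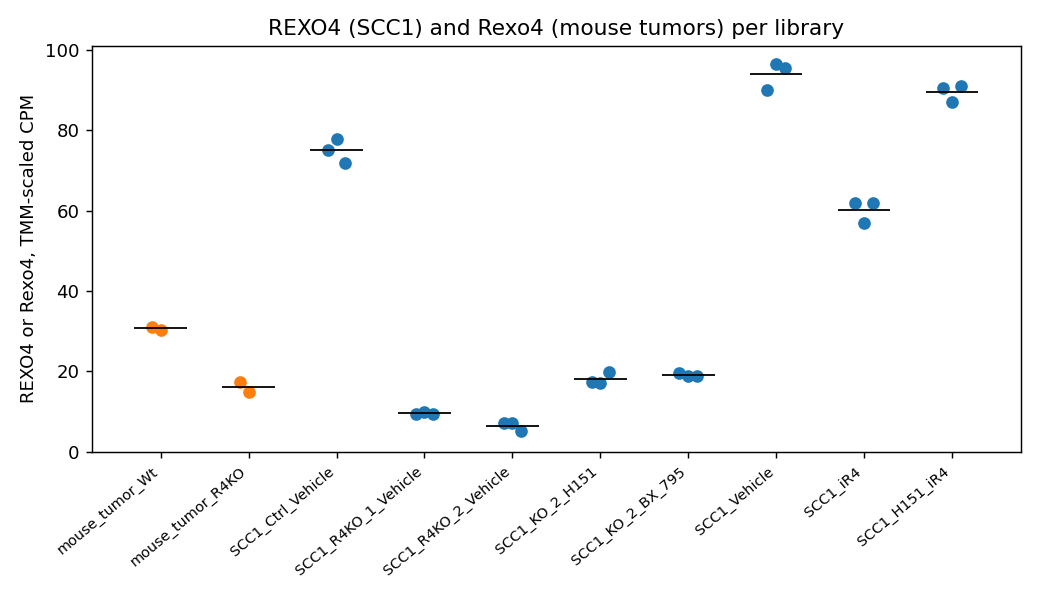
REXO4 (SCC1) or Rexo4 (mouse) in TMM-scaled CPM on the vertical axis for each library (points) with the group mean (line), by group on the horizontal axis. The mean falls from 74.99 CPM in Ctrl Vehicle to 9.58 in R4KO_1 and 6.40 in R4KO_2, and stands at 60.2 in iR4.

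The mouse comparison asked how Rexo4-knockout tumors differed from wild-type tumors. Interferon-stimulated genes were higher in the R4KO tumors as a list, with a median log2 fold change of 1.82 over 47 genes and 46 of them positive. MHC class II presentation genes had a median of 2.71, with all 10 positive, and MHC class I presentation genes a median of 1.45. Both R4KO tumors also lay above both Wt tumors for T cell markers (median 2.73, 10 of 12 positive), cytotoxic lymphocyte genes (4.16, 4 of 5) and dendritic cell markers (1.36, 7 of 9). Only these 5 of the 16 cytotoxic lymphocyte genes had counts enough to be tested. The filter asked for counts in 2 libraries, so a gene could enter through the R4KO tumors alone. Klrk1, with 58 counts in R4KO and 0 in Wt, did so. Such entries can raise the median of a short list. Basal keratinocyte genes were lower in the R4KO tumors, with a median of -0.56. Macrophage and monocyte markers had a median of 0.93, with all 18 positive, but the groups overlapped: relative to the mean of the tumors the list stood at 0.0147 and 1.24 in R4KO and at -1.25 and 0.0716 in Wt, and its call was lost without R4KO replicate 2 (camera adjusted p = 0.0577) or Wt replicate 1 (0.0710). Cytosolic ribosomal proteins had a median of -0.44 and none of 42 positive, which R4KO replicate 1 carried (-0.65, against 0.19 in R4KO replicate 2 and 0.18 and 0.30 in Wt); without it the camera adjusted p was 0.167. By camera with a preset correlation, 15 of 42 lists were higher and 7 lower, with adjusted p = 7.89e-26 for the interferon list and 1.87e-13 for both MHC lists. No list was called with an estimated correlation, where the adjusted p of these lists ran from 0.57 (interferon and both MHC lists) to 0.91.

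Single genes in the tumors did not pass the threshold. Of 14523 genes tested with edgeR, 0 were called after Benjamini-Hochberg adjustment, 655 had an unadjusted p under 0.05, and DESeq2 called 161. On simulated mouse data DESeq2 made 44 false calls, so some of the 161 may be false. Gbp2 stood at 75.1 ± 34.4 CPM in R4KO against 3.69 ± 1.15 in Wt (n = 2 each), a log2 fold change of 4.35 with an edgeR adjusted p = 0.96. Cxcl9 was at 42.0 ± 2.34 against 0.397 ± 0.562 CPM, Cxcl10 at 23.4 ± 8.43 against 0.721 ± 0.177, and Nlrc5 at 63.3 ± 2.73 against 6.69 ± 3.55. Tap1 (63.9 against 14.3 CPM), Zbp1 (5.66 against 0.595) and Ifih1 (12.6 against 3.04) were also higher in both R4KO libraries than in both Wt libraries. Klrk1 had 58 counts in the R4KO tumors and 0 in the Wt tumors, at least 16.9-fold higher against a floor of 3 counts over the group. The T cell receptor gene Trbc2 ran against its list, at 16.2 ± 8.64 CPM in R4KO and 73.1 ± 17.7 in Wt. Rexo4 had a log2 fold change of -0.93 and an edgeR adjusted p = 0.999. Adjusted over the list alone, 9 interferon-stimulated genes, 9 MHC class I genes and all 10 MHC class II genes passed, against 0 of each over all genes.

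Among the cell type markers, the lowest-p members included Ccr2 (15.2 against 2.57 CPM), Itgax (13.6 against 2.95), H2-Eb1 (134 against 20.0), Cd244a (4.58 against 0.731), Blk (1.02 against 0.222), Dcn (147 against 59.8), Slc2a4 (27.8 against 15.5) and Lpo (2.69 against 0.260), all higher in R4KO. Tie1 (23.6 against 43.2 CPM), Gata2 (3.78 against 5.68), Mmp9 (6.46 against 50.9), Ncam1 (3.85 against 21.2) and Hba-a2 (2.01 against 5.50) were lower. Several ran against their lists: Dcn (3 of 12 fibroblast markers positive), Lpo (1 of 4 gland markers), Blk (1 of 3 B and plasma cell markers), Mmp9 (7 of 9 neutrophil markers), Ncam1 (6 of 9 Schwann and nerve markers) and Gata2 (4 of 7 mast cell markers). Ttn was at 147 ± 207 CPM in R4KO and 4.77 ± 4.67 in Wt, because R4KO replicate 1 was the tumor richest in skeletal muscle transcripts. The first principal component took 47.2% of the variance and set Wt replicate 1 apart from the other 3 tumors.

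**Figure D2:**
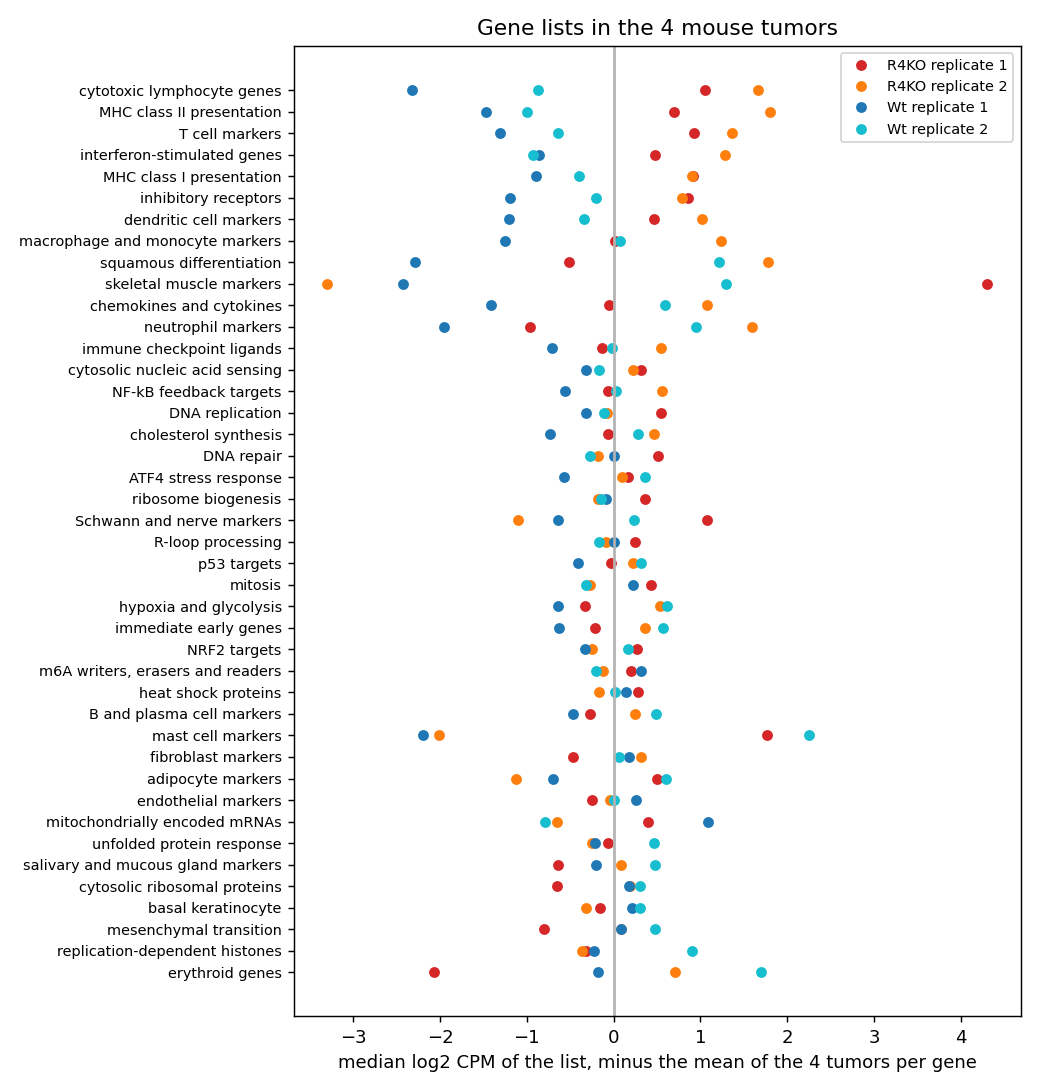
Median log2 CPM of each gene list after subtracting each gene's mean over the 4 tumors (horizontal axis), one point per tumor, with lists on the vertical axis. For interferon-stimulated genes both R4KO tumors (0.48 and 1.28) lie above both Wt tumors (-0.86 and -0.93).

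The R4KO_1 comparison asked how REXO4-knockout SCC1 cells differed from control cells. Interferon-stimulated genes rose, with 47 of 53 higher and 1 lower, while ribosome biogenesis genes fell, with 39 of 40 lower. Ribosomal protein genes fell as well (40 of 42 lower), as did mitosis genes (28 of 30). Cholesterol synthesis genes rose (23 of 25 higher), and 15 of 20 chemokine and cytokine genes rose. R-loop processing genes had a median log2 fold change of -0.21 (20 of 30 lower) and m6A writers, erasers and readers one of -0.25 (14 of 21 lower). By edgeR, 4742 of 14348 genes were higher and 4510 lower, 1086 and 366 of them by 2-fold or more. Camera with the preset correlation called 8 lists up and 10 down, with adjusted p = 1.07e-22 for ribosome biogenesis. With an estimated correlation it called none: the adjusted p of these lists ran from 0.0597 (ribosome biogenesis) to 0.489, with 0.132 for interferon-stimulated genes.

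REXO4 fell in R4KO_1 by 2.97 on the log2 scale, with an edgeR adjusted p = 1.71e-17. OASL rose from 36.5 ± 2.90 to 256 ± 64.1 CPM (n = 3), RIGI from 27.1 ± 2.62 to 125 ± 36.2 and PARP9 from 68.4 ± 2.41 to 138 ± 4.81. RSAD2 rose by 5.47 on the log2 scale (edgeR adjusted p = 4.36e-12), CMPK2 by 4.27, GDF15 by 3.91, S100P by 3.96, IL6 by 2.69 and CSF1 by 1.33. PXDN had 2 counts in all of Ctrl Vehicle and was 208-fold higher in R4KO_1 (95% counting interval 57.2 to 1722), and CCL20, with 3 counts, was 20.2-fold higher (6.61 to 100.4). SLC12A3 rose by 5.18. ACAT2, whose ends SOD2 and TCP1 overlap on the other strand, rose by 3.40 from only 10 counts per control library; how reads shared with those genes were counted is not given in the sources used here. INSIG1 rose by 1.98, HLA-F by 1.07, TAPBP by 0.87 and SAMHD1 by 0.67. DHRS2 fell by 3.60, TMEM45A fell by 2.48, LINC00641 fell by 2.38, EGR3 fell by 2.29 and TRIM66 fell by 2.28. PLK1 fell by 1.54, CDC20 fell by 1.34, RRS1 fell by 1.32, PES1 fell by 1.19, RPL23 fell by 0.94 and RPL24 fell by 0.80.

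The R4KO_2 comparison put the same question to the other knockout. Again the interferon list rose (45 of 53 higher, 1 lower), and all 40 ribosome biogenesis genes and all 42 ribosomal protein genes were lower. Mitosis genes fell in 28 of 30 cases, and 22 of 25 cholesterol synthesis genes rose. By edgeR, 4872 genes were higher and 4623 lower, 1178 and 452 of them by 2-fold or more. Camera called 9 lists up and 7 down with the preset correlation. Ribosome biogenesis and ribosomal proteins kept their call with an estimated correlation, each with adjusted p = 0.0452. The other called lists lost theirs, with an adjusted p of 0.123 for interferon-stimulated genes and of at most 0.301.

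REXO4 fell in R4KO_2 by 3.55 on the log2 scale (edgeR adjusted p = 1.60e-18). ANKRD1 rose by 5.63 and HSPA6 by 5.21, from 1.38 ± 0.114 to 51.5 ± 11.9 CPM (n = 3). RSAD2 rose by 4.67, GDF15 by 4.53, CMPK2 by 3.45, IL6 by 2.93, OASL by 2.81, RIGI by 2.28, IFIH1 by 1.13, CSF1 by 1.20 and PARP9 by 0.98. CCL20 was 34.8-fold higher (95% counting interval 11.6 to 171) and ESM1 33.6-fold higher (11.2 to 165), each from 3 counts in the controls. TM7SF2 rose by 1.92, HLA-F by 1.23 and HLA-E by 0.62. The small nucleolar RNA host gene SNHG3 fell by 2.58 (edgeR adjusted p = 7.04e-19), SNHG26 fell by 2.32 and SNORA73B fell by 2.36. DHRS2 fell by 2.76, LINC00641 fell by 2.73, PLK1 fell by 1.58, CDC20 fell by 1.46, RPL23 fell by 1.31, NPM1 fell by 1.31, PES1 fell by 1.27 and RPL24 fell by 1.01.

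Both knockouts changed largely the same genes. The number higher in both was 3764 and the number lower in both 3686, where independent lists would share 1610 and 1453. Another 154 genes were called in opposite directions. Log2 fold changes correlated across genes at r = 0.83, while unchanged groups simulated against the same controls gave r = 0.52. The covariance was 0.418 against 0.0126 in the simulation, a difference of 0.405. The simulation carries the spread between control libraries but no trait that all of them share, and the controls were not split between the knockouts. Part of the excess may therefore come from the shared controls. At 2-fold or more, 775 genes were higher in both and 244 lower in both. The knockouts also differed from each other, with 2160 genes higher and 2380 lower in R4KO_2 than in R4KO_1 by edgeR. HSPA6 was higher in R4KO_2 by 3.54 on the log2 scale and ESM1 by 4.67, while PXDN (-5.79) and SLC12A3 (-4.89) were higher in R4KO_1.

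**Figure D3:**
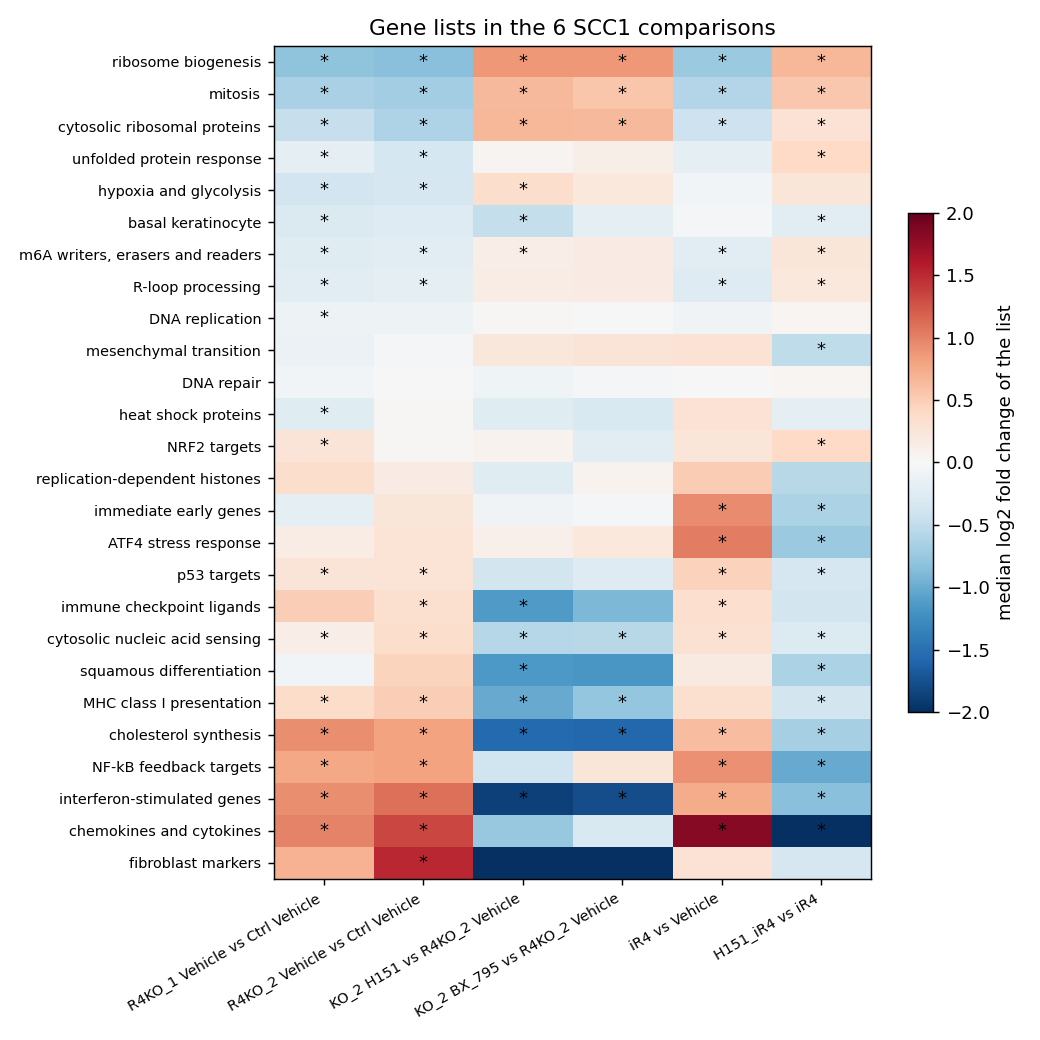
Median log2 fold change (colour) of each gene list (vertical axis) in the 6 SCC1 comparisons (horizontal axis), with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Ribosome biogenesis is at -0.80 and -0.83 in the knockouts against Ctrl Vehicle, and at 0.87 in KO_2 H151 against R4KO_2 Vehicle. Against Ctrl Vehicle, which the figure does not show for KO_2 H151, its median was 0.079.

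Inhibitors were given to KO_2 cells to ask which changes depend on STING signalling. With H-151, 49 of 53 interferon-stimulated genes fell relative to R4KO_2 Vehicle, with a median log2 fold change of -1.86, and 16 of 20 MHC class I genes and 23 of 25 cholesterol synthesis genes fell. Ribosome biogenesis genes rose in 39 of 40 cases, ribosomal proteins in 40 of 42 and mitosis genes in 28 of 30. With BX-795, 50 of 53 interferon-stimulated genes and 23 of 25 cholesterol synthesis genes fell, and 39 of 40 ribosome biogenesis genes rose. By edgeR, 5127 genes were higher and 5303 lower in KO_2 H151 than in R4KO_2 Vehicle (768 and 1426 by 2-fold or more), and 5227 and 5330 in KO_2 BX_795 (856 and 1326). Any difference between the cultures other than the drug is part of these values, since no group separates them. Camera called 12 lists with H-151 and 7 with BX-795. No list kept its call with an estimated correlation, where adjusted p ran from 0.0557 to 0.422 for the lists called with H-151 and from 0.0581 to 0.244 for those called with BX-795. Libraries of drug-treated KO_2 cells were deeper, at 21.36 to 27.94 M counts, than the 17.53 to 17.67 M of R4KO_2 Vehicle. They also held transcripts seen in the other knockout: 58 genes high in R4KO_1 but not in Ctrl or R4KO_2 had a median log2 CPM of 0.42 in KO_2 H151 and 0.44 in KO_2 BX_795, against -1.63 in R4KO_2 Vehicle and 0.73 in R4KO_1 Vehicle.

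**Figure D4:**
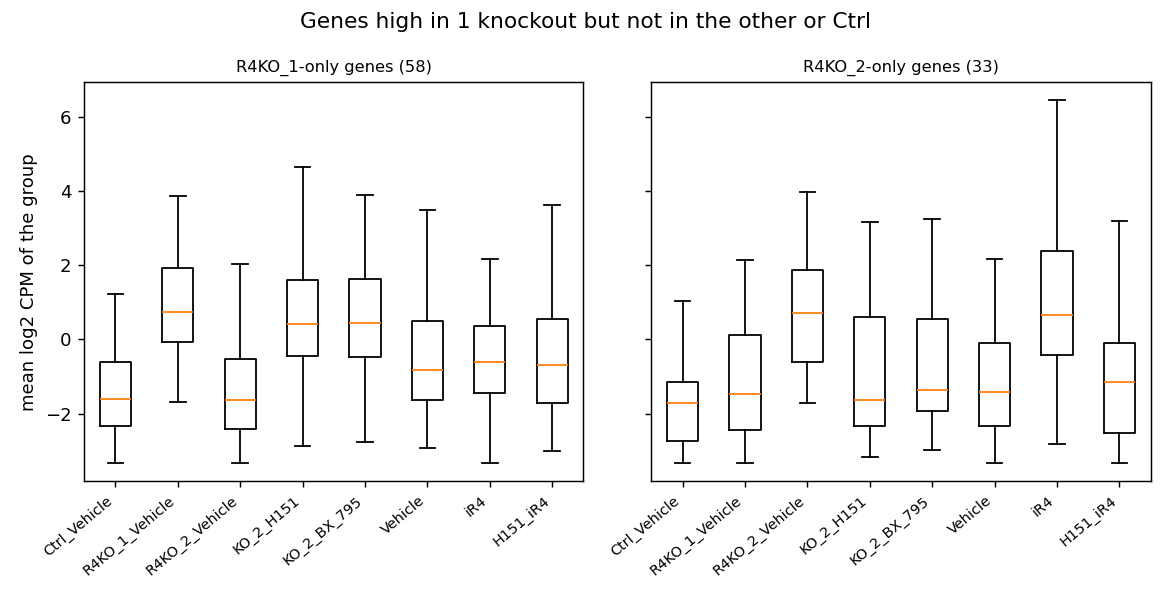
Mean log2 CPM (vertical axis) of the 58 genes high in R4KO_1 but not in Ctrl or R4KO_2 and the 33 high in R4KO_2 but not in Ctrl or R4KO_1, as boxes (median, quartiles, whiskers without outlying points) for each SCC1 group (horizontal axis). The median of the first set is 0.42 in KO_2 H151 and -1.63 in R4KO_2 Vehicle.

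Under H-151, OAS2 fell from 21.7 ± 3.41 to 0.723 ± 0.315 CPM (n = 3) and IFIH1 from 48.8 ± 2.13 to 13.1 ± 0.332. HSPA6 fell by 5.11 on the log2 scale (edgeR adjusted p = 4.43e-16), LINC03040 fell by 4.84, LINC01843 fell by 4.82, RSAD2 fell by 4.74 and BLNK fell by 4.71. MSMO1 fell by 3.12, IFI44L fell by 2.90, TM7SF2 fell by 2.85, HLA-F fell by 2.35, TNFSF10 fell by 2.10, RIGI fell by 3.44 and PARP9 fell by 1.87. NPM1 rose from 1041 ± 10.1 to 3051 ± 43.5 CPM, CDC20 by 1.68 on the log2 scale, PLK1 by 1.61, RRP9 by 1.40, RPL38 by 1.24 and RPL23 by 1.09. Several genes rose far above R4KO_2: SLC12A3 by 6.53, PXDN by 6.21, DHRS2 by 4.21, KRT81 by 4.20, CXCL3 by 3.53 and EID3 by 3.21. SLC12A3 and PXDN are among the genes high in R4KO_1 but not in Ctrl or R4KO_2, so their rises may not be effects of H-151. SLC12A3 was not particular to R4KO_1, however, with a mean log2 CPM of 2.81 in Vehicle of the iR4 experiment and 2.89 in R4KO_1. It also went from 1.55 in iR4 to 3.24 in H151_iR4. CCL20, already higher in R4KO_2 than in Ctrl, rose further by 2.42. REXO4 rose by 1.5004 (edgeR adjusted p = 5.34e-12).

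Under BX-795, OASL fell from 255 ± 25.2 to 7.43 ± 0.5998 CPM (n = 3), HERC5 from 54.5 ± 6.82 to 2.06 ± 0.337 and IFIH1 from 48.8 ± 2.13 to 15.1 ± 0.960. HSPA6 fell by 5.13 on the log2 scale (edgeR adjusted p = 3.98e-16), LINC01843 fell by 4.91, RSAD2 fell by 4.79, LINC03040 fell by 4.61, RIGI fell by 3.41, TM7SF2 fell by 3.30 and MSMO1 fell by 3.19. IFI44L fell by 2.69, HLA-F fell by 2.15, TNFSF10 fell by 2.10 and PARP9 fell by 1.80. PXDN rose by 6.41, SLC12A3 by 5.78, KRT81 by 4.83, CXCL3 by 3.49, DHRS2 by 3.37, MFAP5 by 3.36 and CCL20 by 3.17. PXDN and SLC12A3, high in R4KO_1 but not in Ctrl or R4KO_2, may not owe these rises to BX-795. SLC12A3 was also high in Vehicle of the iR4 experiment, at a mean log2 CPM of 2.81. CDC20 rose by 1.54, AURKA by 1.52, NPM1 by 1.51, PES1 by 1.38, RPL38 by 1.30 and RPL23 by 1.08. REXO4 rose by 1.57 (edgeR adjusted p = 1.99e-12).

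Set beside each other, BX-795 and H-151 libraries differed in 814 genes higher and 573 lower with BX-795, of which 65 and 2 by 2-fold or more. MHC class I genes were higher with BX-795 (7 of 20 higher, 1 lower, median 0.17) and NRF2 targets lower (16 of 25 lower, median -0.28), with camera adjusted p = 0.0258 and 0.0182 under an estimated correlation. NF-kB feedback targets (13 of 19 higher, median 0.50) had a camera adjusted p = 0.127 there. Against Ctrl Vehicle, 3735 genes were higher and 3864 lower in KO_2 H151, and 3976 and 4020 in KO_2 BX_795, with drug and culture again not separated. MHC class I genes lay below Ctrl Vehicle with H-151 (17 of 20 lower, median -0.69, camera adjusted p = 0.0195 with an estimated correlation) and with BX-795 (15 of 20 lower, adjusted p = 0.115). Interferon-stimulated genes lay below it with H-151 as well (42 of 53 lower, median -0.58), though not called with an estimated correlation (adjusted p = 0.460). CXCL3 lay above Ctrl by 4.85 on the log2 scale with H-151 and by 4.80 with BX-795.

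Genes changed in R4KO_1, whose libraries enter none of the inhibitor or iR4 comparisons, were followed there as a pair of sets. Of the 4742 genes higher in R4KO_1, 3070 fell and 657 rose with H-151 in KO_2 cells, and 3014 fell and 748 rose with BX-795. Of the 4510 lower genes, 3011 rose and 597 fell with H-151, and 2975 rose and 631 fell with BX-795. In iR4 cells 4563 of the higher genes were tested, of which 3351 rose and 270 fell, and 3424 of 4472 lower genes fell while 268 rose. Adding H-151 to iR4 turned this round, with 3194 of the 4563 falling and 3307 of the 4472 rising.

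The iR4 comparison asked how iR4 changed SCC1 cells relative to Vehicle. Ribosome biogenesis genes fell in all 40 cases, ribosomal proteins in 41 of 42 and mitosis genes in 29 of 30. Interferon-stimulated genes rose in 44 of 53 cases, chemokines and cytokines in 15 of 18 and NF-kB feedback targets in 16 of 19. ATF4 stress response genes rose as well, with 24 of 29 higher and a median log2 fold change of 1.03, and 20 of 29 immediate early genes rose. By edgeR, 5197 of 14000 genes were higher and 4875 lower, 1201 and 411 of them by 2-fold or more. Camera called 9 lists up and 5 down with the preset correlation and none with an estimated one, where the adjusted p of these lists ran from 0.0578 (mitosis) to 0.326.

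In iR4 cells GDF15 rose from 2.71 ± 0.112 to 154 ± 17.7 CPM (n = 3; edgeR adjusted p = 7.23e-24), INHBE from 3.18 ± 0.759 to 112 ± 10.5 and HSPA6 from 1.13 ± 0.354 to 88.1 ± 31.5. BEST1 rose by 4.38 on the log2 scale, FGF21 by 4.36, RSAD2 by 4.16, IL6 by 4.11, SPRY4 by 4.09, IL1A by 2.85, IL11 by 2.45, OASL by 2.19, RIGI by 2.02 and IFI16 by 0.63. LINC00641 fell by 3.04, SLC19A1 fell by 2.77, SNHG3 fell by 2.52, LINC01963 fell by 2.49, LNP1 fell by 2.41 and TMEM45A fell by 2.12. PLK1 fell by 1.37, HMMR fell by 1.36, UTP20 fell by 1.18, UTP14A fell by 1.15, RPL23 fell by 0.94 and RPL6 fell by 0.71. The chaperones CALR and CANX fell by 0.50 and fell by 0.42. REXO4 fell by 0.64 (edgeR adjusted p = 9.12e-13).

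The iR4 effect was also tested against the R4KO_2 effect. By edgeR, 1626 genes had a higher log2 fold change with iR4 and 1331 a lower one. ATF4 stress response genes (26 of 29 higher, median difference 0.81) and immediate early genes (22 of 29, median 0.92) responded more to iR4, with adjusted p = 0.0932 and 0.155 under an estimated correlation. Interferon-stimulated genes responded less, with 17 of 53 lower, 1 higher and a median difference of -0.27 (adjusted p = 0.367 with an estimated correlation). The REXO4 difference was 2.91 (edgeR adjusted p = 1.60e-19).

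Adding H-151 to iR4 asked which iR4 changes depend on STING signalling. Of 53 interferon-stimulated genes 46 fell relative to iR4, and so did 15 of 18 chemokines and cytokines, 16 of 19 NF-kB feedback targets and 24 of 29 ATF4 stress response genes. Ribosome biogenesis genes rose in 39 of 40 cases and mitosis genes in 29 of 30. NRF2 targets rose in 21 of 25 cases. By edgeR, 4916 genes were higher and 5076 lower, 433 and 1291 of them by 2-fold or more. Camera called 7 lists up and 12 down, and mitosis and NRF2 targets kept their call with an estimated correlation, both with adjusted p = 0.0356. The other called lists had an adjusted p of up to 0.306 there, with 0.0714 for interferon-stimulated genes.

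OASL fell from 151.1 ± 12.5 CPM in iR4 to 2.31 ± 0.968 in H151_iR4 (n = 3; edgeR adjusted p = 1.28e-23), ISG15 from 221 ± 8.96 to 35.2 ± 1.999 and ATF3 from 354 ± 61.5 to 22.7 ± 3.34. HSPA6 fell by 5.79 on the log2 scale, RNASE7 fell by 4.91, RSAD2 fell by 4.89, TNFRSF9 fell by 4.88, GDF15 fell by 4.74, IL6 fell by 4.63, IL1B fell by 3.77, IL1A fell by 3.45, RIGI fell by 3.06 and DHX58 fell by 2.50. SLC19A1 rose by 2.90, LINC00641 by 2.77, DHRS2 by 2.68, LNP1 by 2.59, SNHG3 by 2.48 and LINC02593 by 2.33. ASPM rose by 1.38, PLK1 by 1.29, UTP14A by 1.11, UTP20 by 1.10, RPL23 by 0.90, CANX by 0.71, CALR by 0.66 and RPL24 by 0.63. REXO4 rose by 0.57 (edgeR adjusted p = 1.24e-11).

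H151_iR4 cells lay close to Vehicle, with 1220 genes higher and 1341 lower by edgeR, 37 and 78 of them by 2-fold or more. OASL had a log2 fold change of -3.82 against Vehicle and ISG15 one of -1.32. NRF2 targets were higher than in Vehicle in 22 of 25 cases, with a median of 0.60 and adjusted p = 1.7e-04 with an estimated correlation, and unfolded protein response genes in 15 of 20, with adjusted p = 0.00629. Mesenchymal transition genes (11 of 21 lower, 0 higher, median -0.28, camera adjusted p = 0.0128) and basal keratinocyte genes (15 of 19 lower, median -0.33, 0.0282) were lower than in Vehicle, also with an estimated correlation.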

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

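The splits of the libraries reported in this part were counted after the results were seen; the test of the difference was planned.

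H-151 had unlike effects in iR4 cells and in KO_2 cells at 7397 of 14585 genes, by an edgeR test of the difference between these groups of cells. For REXO4 the effect in iR4 cells minus that in KO_2 cells was -0.94 on the log2 scale (edgeR adjusted p = 1.9e-08), from a rise of 0.57 in iR4 cells and 1.5004 in KO_2 cells. DHRS2 (-1.53), PLK1 (-0.33) and RPL23 (-0.20) also rose less in iR4 cells. For RIGI, HSPA6 and RSAD2 the difference did not pass (edgeR adjusted p = 0.166, 0.296 and 0.879). Of 53 interferon-stimulated genes, 34 had a higher difference and 5 a lower one, with a median of 0.53 and a camera adjusted p = 1.19e-08, or 0.2305 with an estimated correlation. Among 13839 genes tested in every fit, 6682 were called the same way with H-151 in both kinds of cell. Another 1053 were called in opposite ways and also passed the test of the difference. MHC class I genes had a higher log2 fold change with H-151 in iR4 cells than in KO_2 cells (19 of 20 higher differences, camera adjusted p = 0.00253 with an estimated correlation). Since the KO_2 drug libraries hold genes high in R4KO_1 but not in Ctrl or R4KO_2, at a median position of 0.854 from R4KO_2 to R4KO_1, these differences may not be effects of H-151.

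Other splits of the same libraries were too few for a share under 0.05 in any pairwise comparison: of 10 splits each, 1 (the real one) called as many genes, and the highest other called 0. For the differences between experiments, 25 splits were drawn. As many genes as the real 7397 were called in 2 of them for the H-151 difference (highest other 7902), and as many as the real 2957 in 5 of them for iR4 minus R4KO_2 (highest other 8004). Each of those other splits kept the real grouping of 1 experiment, whose effect it carries, and splits that kept neither called at most 0. Splits that kept neither put the real group differences into the spread within groups, which lowers their counts. Neither kind of split therefore decides whether the differences between experiments are real.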

How the results depend on the processing

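Leaving out libraries from the gene list tests, and fry for the R4KO_1 sets, were chosen after seeing the data. So were the replicate block and leaving out libraries for the genes shared by both knockouts. The other settings were planned. Counts of called genes and lists were held to within 1.5 times the reported value, and R4KO_1 set tests to their direction and call. By these rules 199 cases stayed the same and 19 counts moved further. REXO4 kept its direction in all 101 cases and its call in those of SCC1. In mouse Rexo4 had no call to keep. Over the other settings R4KO_1 gave 8320 to 9440 genes, R4KO_2 8898 to 9738, H-151 in KO_2 cells 9860 to 10907, BX-795 10005 to 11067, iR4 9107 to 10426 and H151_iR4 9074 to 10400. A minimum of 2-fold left 1452, 1630, 2194, 2182, 1612 and 1724 genes in that order, and 1019 in both knockouts, by its own construction. In mouse, no filter gave 6 genes (5 higher, 1 lower) and DESeq2 161 (95 higher, 66 lower). On simulated mouse data DESeq2 made 44 false calls against 3 with edgeR. Why the counts differ in the real data was not tested. With an estimated correlation the number of gene lists called was 0 in mouse, 0 in R4KO_1, 2 in R4KO_2, 0 with H-151 in KO_2 cells, 0 with BX-795, 0 in iR4 and 2 in H151_iR4; the cause was not tested. Fry called 0 lists in mouse, 21 with H-151 in KO_2 cells and 19 with BX-795; the cause was not tested. Of the genes called against Ctrl, 1 turned in R4KO_1 without Ctrl replicate 1, and in R4KO_2 1 without Ctrl replicate 1 and 1 without Ctrl replicate 3; the cause was not tested. Among the named genes and the lists the direction turned only in mouse, where leaving out 1 of 2 libraries leaves a lone tumor assumed to vary like the others: Ttn turned to -3.59 without R4KO replicate 1 (range -3.59 to 6.63), and these lists turned, with the range of their adjusted p: chemokines and cytokines (6.40e-08 to 0.534) and cholesterol synthesis (1.09e-08 to 0.756) without Wt replicate 1, ribosome biogenesis (1.84e-04 to 0.240) without R4KO replicate 1 at 0.201, unfolded protein response (3.98e-06 to 0.757) without Wt replicate 2, and squamous differentiation (1.58e-11 to 0.432) without R4KO replicate 2 and, at 0.00213, without Wt replicate 1. With the replicate number as a block, R4KO_1 gave 9225 genes, R4KO_2 9439, H-151 in KO_2 cells 10392, BX-795 10484, iR4 10058 and H151_iR4 9940. Same-numbered SCC1 libraries did not vary together (correlations from -0.23 to 0.36 over 30 pairs in the knockout experiment and -0.06 to 0.06 over 9 in the iR4 experiment), so the numbers do not pair them. In mouse the correlation was 0.33, a single value that both pairs share by construction with 2 libraries per group, so it does not decide; the block gave 0 genes there.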

Other observations

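Small nucleolar RNA host genes (SNHG) were grouped after SNHG3 and SNHG26 stood out, and all tests of explanations in this part were chosen after the results were seen.

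SNHG transcripts were lower in the knockouts and with iR4. SNHG3 and SNHG26, which led to the grouping, are left out of the values here. Of 17 tested, 14 fell in R4KO_1 and 14 in R4KO_2, with median log2 fold changes of -0.80 and -0.97 (camera p = 0.00279 and 0.00180 with an estimated correlation). Relative to R4KO_2 Vehicle, which both comparisons share, 16 were higher in KO_2 H151 and 17 in KO_2 BX_795, with medians of 1.33 and 1.32 (camera p = 5.44e-04 and 2.54e-04 with an estimated correlation). In the iR4 experiment 13 of 16 fell with iR4 and 12 rose when H-151 was added, with medians of -0.64 and 0.66 (camera p = 0.0495 and 0.0485 with an estimated correlation).

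Genes high in R4KO_1 but not in Ctrl or R4KO_2 were high in the KO_2 drug libraries, as PXDN shows, though just 34 of the 58 lay more than 1 log2 unit above all groups of the iR4 experiment in R4KO_1. Mixing with Ctrl cells does not account for it, since 69.0% lay more than 1 log2 unit above both Ctrl and R4KO_2 with H-151, nor does mixing with Vehicle cells of the iR4 experiment, since 63.8% lay that far above R4KO_2 plus the 18.7% of Vehicle cells that REXO4 allows at most. H-151 raising these genes as a set in SCC1 cells of both experiments is excluded too. Their median log2 fold change in H151_iR4 over iR4 was -0.0346 (quartiles -0.544 and 0.462). Single genes can differ from the set, as SLC12A3 went from a mean log2 CPM of 1.55 in iR4 to 3.24 in H151_iR4. Drug-treated libraries made from R4KO_1 cells (a mislabelled sample) may account for the pattern of the 58 genes. With H-151 the 58 genes lay at a median position of 0.854 from R4KO_2 to R4KO_1 (0.62 for the 34). The 33 genes high in R4KO_2 but not in Ctrl or R4KO_1 lay at 0.0609 from R4KO_1 to R4KO_2. Part of such a position comes from choosing the genes on these groups. Undrugged Vehicle cells had a median log2 CPM of -0.83 for the 58, against -1.63 in R4KO_2. Against R4KO_1 cells, REXO4 at 18.1 CPM lay above the 9.58 CPM of R4KO_1. Of the 33 genes, 4 also lay more than 1 log2 unit above Ctrl and R4KO_1 with H-151. Both inhibitors raising the 58 genes in KO_2 cells alone also stays open and cannot be told apart here. Their median log2 fold change for BX-795 over H-151 was 0.0469.

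H-151 returned lists that iR4 changed toward Vehicle, such as mitosis (median -0.58 with iR4 and -0.03 with H-151 added) and chemokines and cytokines (1.82 and -0.12), while NRF2 targets, not called in iR4, moved further from Vehicle (0.25 and 0.60). With an estimated correlation camera gave adjusted p = 0.0578 for mitosis and 0.0742 for chemokines and cytokines in iR4. Between H151_iR4 and Vehicle libraries 2561 genes were called, 37 higher and 78 lower by 2-fold or more. The count argues against repeats of the same Vehicle culture. It cannot exclude another, mislabelled Vehicle culture, since p-values may measure only technical spread and separate untreated cultures were not compared. A return limited to interferon-stimulated genes is excluded, since the ribosome biogenesis list kept a fraction of 0.101 of its iR4 change. Lower activity of iR4 in the cultures given H-151 could act on all these genes and cannot be told apart from STING inhibition. The median remaining fraction was 0.0301 over the 2-fold genes outside the interferon list. REXO4 returned as well, from 60.2 CPM in iR4 to 89.5 in H151_iR4, against 94.0 in Vehicle.

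Interferon and most leukocyte lists were high in the R4KO tumors by median, and 4 of 8 leukocyte lists separated the groups. MHC class II presentation, which names a function rather than a cell type, is counted among the 8 and among the 4. A single Wt tumor with few immune transcripts does not account for the interferon list, whose median was 1.84 without Wt replicate 1. It may for the neutrophil list, whose median went from 0.83 to 0.0577. MHC class II kept 2.35 of 2.71 and macrophage markers 0.67 of 0.93. B and plasma cell markers went from -0.0834 to -0.485. For other lists more members were tested without that tumor. T cell markers went from 2.73 over 12 genes to 1.97 over 13, and cytotoxic lymphocyte genes from 4.16 over 5 to 2.61 over 8. Dendritic cell markers went from 1.36 over 9 genes to 1.13 over 11, and mast cell markers from 0.36 over 7 to -0.69 over 8. A lower share of tumor cells, which would raise the markers of every other cell type alike, does not account for it either: between any R4KO and any Wt tumor the endothelial and fibroblast lists rose by at most 0.254, while the T cell and MHC class II lists rose by at least 1.56. More cells of the types that rose stays open. Differences between single tumors unrelated to Rexo4 cannot be told apart with 2 tumors per group, where 4 of 8 leukocyte lists had both R4KO tumors above both Wt tumors.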
